A study of Drosophila melanogaster with 48 samples.

How the data were processed

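The series held 48 libraries from the midgut of young female fruit flies (Drosophila melanogaster). Of these, 25 were RNA-seq libraries of sorted intestinal stem cells and 23 were DamID-seq libraries. In DamID, a DNA adenine methyltransferase (Dam) is fused to a DNA-binding protein and marks the DNA near the places the protein visits. Dam alone serves as the control for open chromatin. Per the labels' protocols, flies were raised at 18 °C and shifted to 29 °C at 3 days after eclosion, which switched on a temperature-controlled escargot driver. Su(H)-Gal80 kept the driver off in enteroblasts, the daughters that receive Notch signal. For RNA-seq, the cells sorted were positive for YFP and negative for propidium iodide. DamID DNA came from whole midguts and was digested with DpnI and then DpnII, per the labels' protocols. The treatment text of the labels gives 24 h at 29 °C for every sample, while the titles of 8 RNA-seq samples give 8 h, and the titles were followed here.

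Gene tables and DamID tables were deposited as raw read counts, per the file headers. The RNA-seq table held 17558 genes, and each DamID feature was a window of 75 bp with neighbouring windows sharing reads. The submitters' processing notes name FastQC, STAR 2.6.1d, Bowtie2 2.2.5, HTSeq 0.11.1, DESeq2 1.18.1 and the genome build BDGP6, without saying which tool made which file. Whether counting used strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart, and genes of near-identical families (the Jonah and trypsin proteases, the Hsp70 genes, the lysozymes) may share reads. The Pnt libraries were made with a kit that does not mark strand and the Spitz and Ets21C libraries with a stranded kit, per the labels. The authors' deposited tables of changed genes give mean CPM (counts scaled to the library total) per group, a log2 fold change, a p-value and a Benjamini-Hochberg adjusted p-value per gene. The authors' deposited peak lists give a log2 ratio of fusion to Dam for each peak and the bases it shares with each annotated element, with 1 list per fusion over its replicates. The peak caller and its threshold are not given in the sources used here. Coordinates are those of the deposited files (BDGP6), 1-based.

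Gene symbols came from the deposited tables and, for the rest, from a table of gene names that matched 17252 of the 17558 identifiers; 183 identifiers had a symbol in neither. No column of sample values was left unused.

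RNA-seq counts were tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood F test with group means only, TMM factors and the filterByExpr filter. The Pnt set (control, PntP1, PntP2) and the Spitz and Ets21C set (control, Spitz, Ets21C, at 8 h and 24 h) were fitted apart, and all groups of a set shared 1 estimate of the spread. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Mean CPM values are given with the SD over libraries, fold changes with the SE on the log2 scale, and log2 CPM used a prior count of 2. Against a group with 0 reads the fold is a lower bound from a floor of 3 counts over the group, and with 1 to 3 reads the ratio of summed CPM is given with its 95% exact counting interval. P-values measure the spread between libraries, which the series design calls biological replicates, while intervals and floors cover counting error only. DamID windows were tested in the same way within each set, with the newer edgeR dispersion route.

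Before the data were examined, the groups, tests, alternatives, rule for named genes and 18 gene lists of 471 genes (452 of them in the count table) were fixed. The lists covered stem cell and progenitor markers, Notch targets, enterocyte identity, digestive enzymes, enteroendocrine markers, visceral muscle, blood cell with fat body and ovary markers, EGFR-Ras-MAPK genes, cell cycle, ribosome biogenesis, mitochondrial respiration, JAK-STAT, JNK and wound response, heat shock, glutathione and detoxification, antimicrobial and immune genes, integrin with basement membrane and adhesion, and lipid and carbohydrate metabolism. Each list was tested with camera (limma 3.58.1, correlation preset at 0.01) in the 6 comparisons with control, adjusted over the 108 tests, with fry and camera's estimated correlation beside it. Of the 108 tests 33 passed, 14 upward and 19 downward, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.693. Fry passed 33, of which 24 were the same tests. The median and the camera direction differed in 12 tests, none of them among the 33, and the median and mean differed in sign in 21, again none of the 33.

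The rule named the overexpressed gene, the 8 largest rises and 8 largest falls among called genes with a mean of at least 10 CPM in 1 of the groups and no overlap between the groups' libraries, and up to 4 members of each list with the lowest adjusted p, any list member being allowed. For direct and interaction contrasts it took 5 genes per direction. For DamID it took the 5 windows with the largest rise and the highest window in esg, Dl, pnt, Ets21C, spi, sty, aos, stg and the E(spl) genes, and for peaks the 5 strongest of each list.

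Peak lists were intersected with bedtools 2.31.1 (at least 1 shared base) and set beside 100 shuffles of positions. Whether changed genes carried a peak, by the authors' own assignment of peaks to genes, was tested with Fisher's exact test (two-sided) over the genes tested in RNA-seq, and again over 10 strata of expression or of gene length. Lengths were gene spans, known for 85.4% of the Pnt set's genes and 85.1% of the other set's. Comparisons against the same controls were set beside 10 simulations of unchanged groups. Alternatives were RLE factors, no filter, a filter of 10 CPM, a minimum log2 change of 1, a replicate block, only the compared groups, DESeq2 1.42.0, each library left out in turn and, for DamID, total-count scaling and a minimum of 10 reads in place of the filter. Added after seeing the data were a fit without 2 libraries that stood apart (Spitz at 8 h replicate 1 and control at 24 h replicate 3) and the older edgeR dispersion route for DamID.

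Same-numbered DamID libraries of the Pnt set deviated together, with correlations of 0.195 to 0.64 and 15 of 15 pairs above 0.1, so blocked counts stand beside the results they move. For Ets21C DamID 2 of 4 such pairs were above 0.1 (-0.227 to 0.726), short of the rule that every pair be above 0.1, so no pairing was used there or in RNA-seq.

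The code was tested on simulated counts made from the real means and library sizes, with 200 changed features. These were drawn only from genes above a minimum mean expression, or from windows above the median. The shares recovered therefore do not cover features with few reads. For PntP1 against control (9433 genes) the fit recovered 43.3% of genes changed by 1.5-fold, 95.5% of those changed by 2-fold and 100% of those changed by 4-fold, with 4.79% of calls false. The false share was 8% for PntP2, 10.5% for PntP1 against PntP2, 9.62% for the Ets21C time contrast and 8.57% for Ets21C-Dam, and 2.63 to 6.78% for the rest. For Ets21C at 8 h (10137 genes), with 2 treated libraries, it recovered 26.9%, 79.1% and 89.4%, and for the Ets21C time contrast 2.99%, 55.2% and 83.3%. For Ets21C-Dam (33072 windows, every 20th) it recovered 48.5% of 4-fold changes and 0% of 2-fold changes. RNA-seq depth was 32.92 to 73.11 M counts per library and DamID depth 30.32 to 139.5 M.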

Results

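RNA-seq profiled intestinal stem cells, the self-renewing cells of the adult fly midgut, after overexpression of 1 of 4 proteins. PntP1 and PntP2 are 2 isoforms of Pointed, an ETS transcription factor of the EGFR pathway. Ets21C is another ETS factor, and Spitz (spi) is a secreted EGFR ligand. The Pnt set had 3 control, 3 PntP1 and 2 PntP2 libraries at 24 h. A second set had 3 control, 3 Spitz and 2 Ets21C libraries at 8 h, and 3 of each at 24 h. DamID mapped sites visited by Ets21C-Dam (4 libraries, with 4 of Dam alone) and by PntP1-Dam and PntP2-Dam (5 each, with 5 of Dam alone). The sets were never compared by level: control Ets21C ran at 384.7 to 767.4 CPM in the second set, against 6.408 to 17.52 CPM in all libraries of the Pnt set.

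Each overexpressed gene was higher in its own libraries than in every control. Reads of pnt (FBgn0003118), which do not separate isoforms or transgene from native gene, rose from 408.7 ± 28.8 CPM (SD, n = 3) to 1776 ± 436 CPM with PntP1 (n = 3), 4.35-fold, and to 1038 ± 49 CPM with PntP2 (n = 2), 2.54-fold. Ets21C (FBgn0005660) rose 2.73-fold at 8 h, from 646.7 ± 122 to 1763 ± 304 CPM (n = 3 and 2), and 2.11-fold at 24 h, from 488.7 ± 166 to 1031 ± 20.3 CPM (n = 3 each). Transcripts of spi (FBgn0005672) rose 3.55-fold at 8 h and 2.82-fold at 24 h, to 1148 ± 68 and 874.8 ± 52.4 CPM (n = 3 each). SEs on the log2 scale were 0.161 and 0.171 for pnt, 0.254 and 0.233 for Ets21C, and 0.117 and 0.116 for spi.

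**Figure D1:**
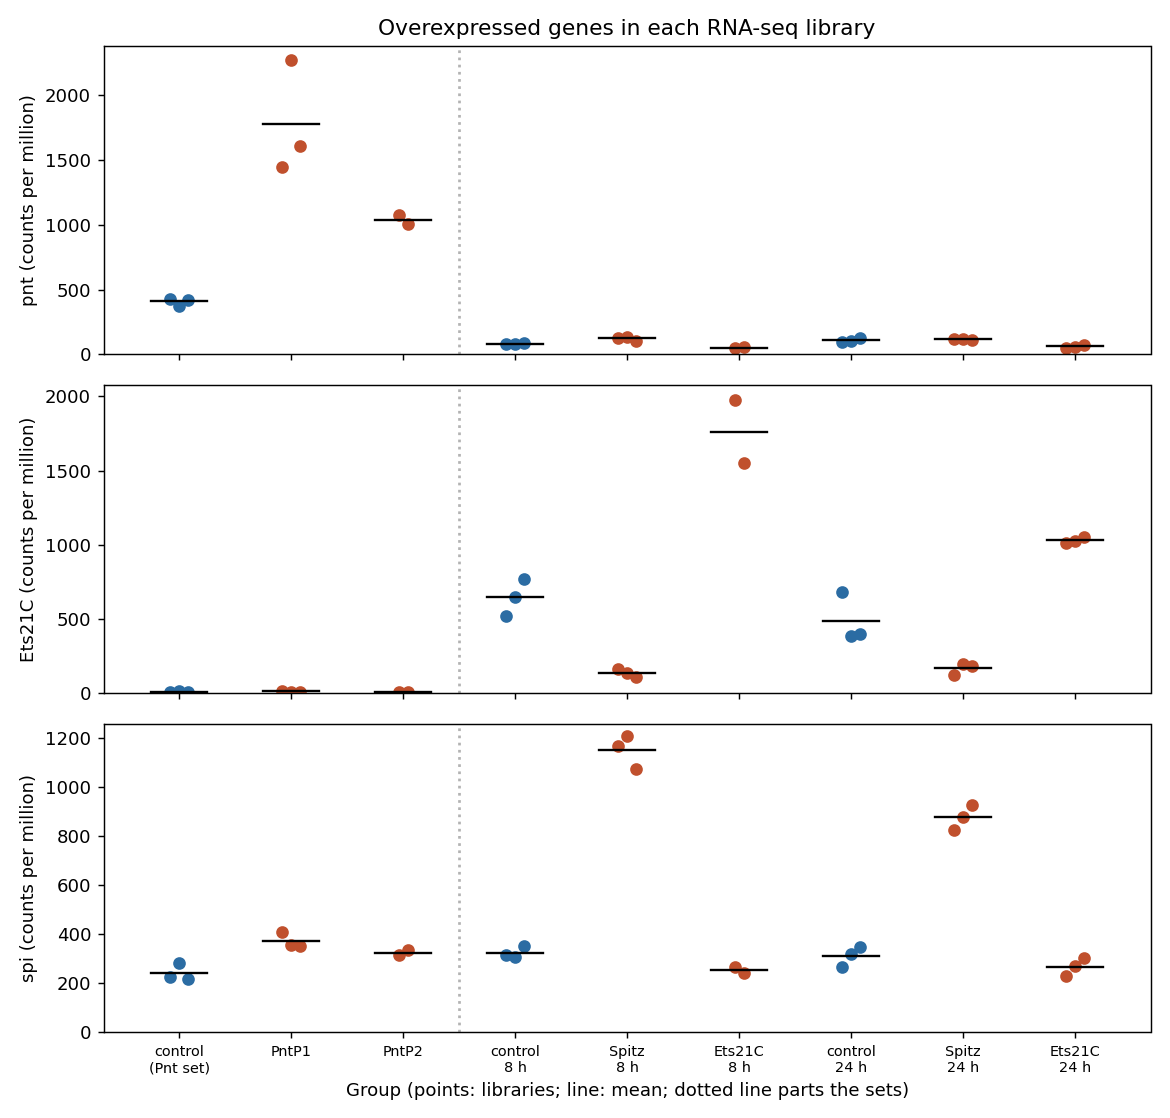
CPM of pnt, Ets21C and spi on the vertical axes in each RNA-seq library, by group on the horizontal axis; points are libraries, lines are means, and the dotted line parts the 2 sets. The 3 PntP1 libraries lie between 1448 and 2270 CPM for pnt, and Ets21C lies between 110.5 and 195 CPM in all Spitz libraries.

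The first comparison asked which genes PntP1 changed in stem cells. The neuronal and adhesion genes Cadps, a vesicle-release factor, and kirre, an immunoglobulin-type adhesion protein of muscle founder cells, rose 11.7-fold (113.2 vs 9.659 CPM, SE 0.176) and 10.7-fold (368.5 vs 34.32 CPM, SE 0.222; n = 3 each). The peptide hormone gene Lst rose 15.4-fold and the uncharacterised CG13670 15.3-fold, from 2.531 and 3.024 CPM. The matrix metalloprotease Mmp2 rose 8.52-fold (249.8 vs 29.32 CPM, SE 0.21) and edl, an antagonist of Pointed activity, 6.12-fold (584.1 vs 95.38 CPM, SE 0.127). In the other direction CG6912 fell 6.57-fold, the neuropeptide-like precursor Nplp2 4.9-fold, the juvenile hormone epoxide hydrolase gene Jheh1 4.5-fold and the Notch target E(spl)mgamma-HLH 4.01-fold. Other large changes were rises of CG4250 (11.2-fold), CR31451 (10.4-fold), Tsp5D (10.3-fold) and CG43795 (10.2-fold), and falls of Cyp6w1 (4.45-fold), CG30043 (4.05-fold), CG9021 (3.69-fold) and Culd (3.64-fold). Of 9639 genes tested, 3059 changed (31.7%), 1632 higher and 1427 lower, and 914 of them by at least 2-fold. Without PntP1 replicate 1 the count was 1852.

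Among 49 cell cycle genes 29 rose and 2 fell with PntP1 (33 and 2 adjusted over the list alone; median log2 change 0.76, camera adjusted p = 4.8e-09, adjusted p = 0.838 with an estimated correlation). The replication clamp PCNA rose 3.24-fold (519.1 vs 160.2 CPM), the mitotic kinase Cdk1 2.82-fold, the checkpoint gene mad2 2.64-fold and the securin pim 2.48-fold. Heat shock genes went down, with 9 of 18 lower and 0 higher (0 and 11 adjusted over the list alone), the median having dropped by 0.71 on the log2 scale (adjusted p = 0.00195; adjusted p = 0.838 with an estimated correlation). The small chaperone genes Hsp26 and Hsp27 fell 2.45-fold and 2.2-fold, and the list summed to 38480 to 43700 CPM in controls and 15460 to 27380 CPM with PntP1. Genes named as ribosomal RNA moved with the same groups, with 2.66 to 3.06% of reads in controls, 1.76 to 2.14% with PntP1 and 1.72 and 2.13% with PntP2. Notch targets also fell, 5 of 12 with none higher and the same counts adjusted over the list alone (adjusted p = 0.00672; adjusted p = 0.838 with an estimated correlation), among them klu by 1.91-fold and E(spl)mbeta-HLH by 1.52-fold.

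The other 15 lists did not pass with PntP1, though several members moved. Among 29 EGFR-Ras-MAPK genes 10 rose and 7 fell, the protease gene rho by 4.4-fold upward and the phosphatase gene Mkp3 by 3.12-fold upward. Of the 14 stem cell markers 3 rose and 4 fell: mira, which segregates cell fate determinants, fell 3.1-fold, jumu rose 3.02-fold and the receptor gene Pvr rose 2.13-fold. JAK-STAT genes split 2 to 2 of 10, with upd3 up 2.6-fold, upd1 up 4.98-fold and Stat92E down 1.92-fold. Of 18 JNK and wound genes 6 rose and 3 fell, the TNF receptor gene grnd rising 6.65-fold. Integrin and adhesion genes counted 6 up and 4 down of 21 (if up 5.85-fold, Fas2 up 3.23-fold, LanA down 2.29-fold), and lipid and carbohydrate genes 2 up and 7 down of 23 (bmm, a triglyceride lipase, down 3.16-fold). Enteroendocrine markers rose in 4 and fell in 1 of 25 (sc up 2.51-fold), and their sum was 771.8 to 1191 CPM with PntP1 against 380.4 and 411.5 CPM in control replicates 1 and 3, with replicate 2 at 882.1 CPM. Counts of higher and lower genes were 4 and 5 of 16 for enterocyte identity, 6 and 6 of 47 for digestive enzymes, 2 and 3 of 18 for muscle, 2 and 2 of 10 for blood, fat body and ovary, 1 and 4 of 28 for ribosome biogenesis, 4 and 2 of 29 for respiration, 3 and 7 of 31 for detoxification and 0 and 3 of 8 for immune genes.

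With PntP2, for which 2 libraries were available, CG13670 rose 4.67-fold (SE 0.181, adjusted p = 5.78e-05), Cadps 4.27-fold, the microtubule-associated futsch 4.24-fold and the carbonic anhydrase gene CAH2 4.11-fold (n = 2 vs 3). CG10178 rose 4.24-fold, Tsp5D 4.2-fold, CG4250 4.1-fold, Mmp2 3.72-fold and edl 2.99-fold. CG6912 fell 11.3-fold (SE 0.427), the lysosomal alpha-mannosidase genes LManIII and LManV 32.4-fold and 4.61-fold, Nplp2 5.53-fold, CG30043 4.72-fold, CG18404 4.42-fold, E(spl)mgamma-HLH 4.07-fold and mira 2.35-fold. The detoxification gene GstS1 rose 2.25-fold and the adhesion gene Fas2 1.91-fold. In all, 1417 genes changed (14.7%), 808 higher and 609 lower, and 408 by at least 2-fold. The count moved to 127 without PntP2 replicate 3, 248 without replicate 1, 925 without control replicate 3 and 2323 without control replicate 2. Of 69 named genes called, 46 lost the call under at least 1 alternative, mostly when either PntP2 library was left out; the genes in this paragraph kept theirs throughout.

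Cell cycle genes rose in 24 of 49 cases with PntP2 and fell in 0 (30 and 0 adjusted over the list alone; median 0.71, adjusted p = 1.42e-10; adjusted p = 0.838 with an estimated correlation), with PCNA up 2.62-fold, mad2 2.26-fold and polo 1.79-fold. Heat shock genes fell in 4 of 18 (0 up and 9 down adjusted over the list alone; adjusted p = 0.00566; adjusted p = 0.853 with an estimated correlation), and their sum was 25650 and 26300 CPM. The 29 respiration genes passed upward as a list (adjusted p = 0.00755; adjusted p = 0.838 with an estimated correlation) with 1 gene called, COX6B, and 0 adjusted over the list alone; that call was lost under 6 alternatives, among them leaving out control replicate 1 or 3, either PntP2 library or the PntP1 group. None of the remaining lists passed. Numbers higher and lower were 1 and 3 of 14 for stem cell markers, 0 and 2 of 12 for Notch targets, 1 and 9 of 47 for digestive enzymes, 4 and 0 of 25 for enteroendocrine markers, 5 and 4 of 29 for EGFR-Ras-MAPK genes, 5 and 1 of 28 for ribosome biogenesis, 1 and 4 of 18 for JNK genes and 2 and 3 of 23 for metabolism.

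Set directly against each other, PntP1 and PntP2 differed at 89 of 9639 genes, 81 of them higher with PntP1. CG18404 was 4.43-fold higher (SE 0.259, adjusted p = 0.00573), Lst 3.68-fold, CG13670 3.26-fold, CG8539 2.96-fold and CG4991 2.76-fold, while the microtubule linker CLIP-190 was 2.83-fold lower, Cpr51A 1.89-fold, Picot 1.87-fold, CDase 1.85-fold and CG5910 1.71-fold lower with PntP1 (n = 3 vs 2). Total pnt reads were 1.71-fold higher with PntP1, which did not pass (adjusted p = 0.0787). Without PntP2 replicate 1 or replicate 3 the count was 0, and without PntP1 replicate 1, 2 or 3 it was 22, 53 or 33, while it was 146 with no filter on low counts, 239 with only these 2 groups and 266 by DESeq2. Both isoforms raised 740 genes and lowered 547, with 0 in opposite directions. Independent lists would share 137 and 90.2. Unchanged groups simulated against the shared controls gave 0, but with no changed gene few can be called, so this sets no bound on the part due to the controls. Fold changes correlated at 0.753 across genes, which are not independent replicates (simulated 0.44), with a covariance of 0.433 (simulated 0.0702); part of the excess may come from the shared controls.

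At 8 h of Ets21C, genes that were close to silent in controls were the ones with the largest rises. CG32305 went from 0.02316 to 44.49 CPM (1690-fold, SE 0.51), CG32301 from 0.02154 to 28.28 CPM (1080-fold), the gustatory receptor gene Gr59e from 0.132 to 89.1 CPM (637-fold) and cn, a kynurenine enzyme of eye pigment synthesis, from 0.07648 to 13.22 CPM (173-fold; n = 2 vs 3). CG34113 rose 424-fold, Cyp309a2 135-fold, CG44098 121-fold and the dynein gene Dnah3 69-fold. Genotype went with the group, so at such near-silent genes a strain variant between the crosses cannot be told apart from an effect of Ets21C. Tektin-C, a ciliary structural gene, fell 37.1-fold, the adhesion gene Dscam4 10.3-fold (118.3 to 11.43 CPM, SE 0.167), CG9021 10.3-fold, hbs 7.36-fold, GstE1 6.02-fold and Cht2 5.91-fold. Of 10382 genes 1620 changed (15.6%), 843 higher and 777 lower, with 542 beyond 2-fold. The count was 585 without Ets21C replicate 1 and 807 without replicate 2.

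Among the lists at 8 h, cell cycle genes rose in 26 of 49 with Ets21C and fell in 0 (34 and 0 adjusted over the list alone; median 0.71, adjusted p = 6.59e-14; adjusted p = 0.792 with an estimated correlation), RnrL and RnrS, both subunits of ribonucleotide reductase, by 2.22-fold and 1.89-fold and Mcm7 by 2.66-fold. Heat shock genes rose in 11 of 18 (14 adjusted over the list alone; median 1.15, adjusted p = 6.07e-06; adjusted p = 0.693 with an estimated correlation), with Hsp67Ba up 10.5-fold and Hsp67Bc 6.26-fold, and summed to 23520 and 25740 CPM against 16890 to 17250 CPM in controls. Respiration genes rose in 13 of 29 (14 adjusted over the list alone; adjusted p = 7.38e-07; adjusted p = 0.838 with an estimated correlation), COX8 by 1.45-fold. Ribosome biogenesis genes passed downward with 3 of 28 lower and 1 higher (adjusted p = 0.00852; adjusted p = 0.905 with an estimated correlation), and digestive enzymes with 1 of 49 lower (0 adjusted over the list alone; adjusted p = 0.0348; adjusted p = 0.957 with an estimated correlation). The digestive enzyme call was lost with the replicate block, and the list summed to 3034, 2464 and 6982 CPM in controls against 2163 and 2244 CPM with Ets21C. Single members of lists that did not pass also changed: Pvr rose 2.01-fold, E(spl)mgamma-HLH 4.97-fold, the proneural gene sc 6.85-fold and the basement membrane collagen Col4a1 8.64-fold. The growth factor gene Pvf1 rose 5.96-fold, and esg, the driver gene's own locus, fell 1.85-fold, a call lost without Ets21C replicate 2. Genes higher and lower were 2 and 1 of 14 for stem cell markers, 4 and 1 of 13 for Notch targets, 4 and 1 of 26 for enteroendocrine markers and 3 and 6 of 30 for EGFR-Ras-MAPK genes.

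After 24 h of Ets21C the same near-silent genes led: Gr59e rose 1030-fold (60.21 vs 0.05521 CPM, SE 0.603), CG32301 at least 1140-fold (17.44 CPM against 0 reads), and CG32305 and CG34113 by ratios of 3180 (95% counting interval 879 to 26200) and 741 (253 to 3590; n = 3 each). CG44098 rose 64.6-fold, the ankyrin gene Ank2 13.2-fold, NtR 11-fold (SE 0.174) and the kinesin adaptor gene Aplip1 10.7-fold. At the near-silent genes a strain variant between the crosses again cannot be told apart from an effect of Ets21C. CG9338 fell 53.8-fold, Tektin-C 24.9-fold, the alpha-glucosidase gene tobi 15.2-fold, hbs 10.5-fold, the glutamate transporter gene Eaat2 10.1-fold, CG9021 9.7-fold and Dscam4 8.22-fold. The fall of lcs, 79.7-fold with an SE of 2.1, was lost without control replicate 1 or 2 or any 1 Ets21C library. Altogether 2283 genes changed (22%), 1192 higher and 1091 lower, and 710 by at least 2-fold.

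Respiration genes rose in 24 of 29 at 24 h of Ets21C, with 0 lower (27 adjusted over the list alone; median 0.41, adjusted p = 4.23e-13; adjusted p = 0.74 with an estimated correlation), COX6B by 1.66-fold (SE 0.08) and ATPsynD by 1.52-fold. Cell cycle genes rose in 17 of 49 and fell in 0 (30 and 0 adjusted over the list alone; adjusted p = 4.8e-09; adjusted p = 0.838 with an estimated correlation), with PCNA up 2.74-fold and RnrL 2.3-fold. Ribosome biogenesis genes passed downward, 8 of 28 lower and 1 higher (adjusted p = 0.0178; adjusted p = 0.916 with an estimated correlation), among them Non1 by 1.76-fold. Digestive enzymes passed downward with 3 of 49 lower and 1 higher (adjusted p = 0.00061; adjusted p = 0.957 with an estimated correlation), and their sum differed within groups, 8374, 7967 and 2288 CPM in controls against 4788, 1248 and 1347 CPM with Ets21C. Without control replicate 3 and the 8 h Spitz library that also stood apart, 16 enzymes were lower and 1 higher, and 12 of 18 muscle genes were lower in place of 1. Lists that did not pass still held called members: klu fell 2.76-fold, E(spl)m4-BFM rose 8.52-fold, sc 9.06-fold, rho 3.27-fold, Col4a1 14.6-fold and the matricellular gene SPARC 2.88-fold, GstE1 fell 4.99-fold and the receptor gene dome 1.85-fold. EGFR-Ras-MAPK genes split 7 up and 8 down of 30, Notch targets 4 and 3 of 13, metabolism 7 and 2 of 24 and integrin and adhesion genes 5 and 2 of 22.

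The Ets21C effect differed between 24 h and 8 h at 1 gene by edgeR, CG9338, whose fall was 10.3-fold deeper at 24 h (SE 0.426, adjusted p = 0.0158). At an unadjusted p under 0.05 the count was 551 genes (5.31%), and DESeq2 called 17. It was 0 without control replicate 1 or 2 or Ets21C replicate 1 of the 8 h groups, and without control replicate 2 or 3 or Ets21C replicate 1 or 3 of the 24 h groups. At both times 596 genes were higher and 590 lower, with 2 in opposite directions (96.8 and 81.7 by independent lists), and fold changes correlated at 0.638 across genes. In simulated data this contrast recovered 55.2% of genes that differed 2-fold, drawn from genes above a minimum mean expression.

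With Spitz at 8 h several DNA replication genes were among the largest rises. Claspin, a replication checkpoint mediator, rose 8.53-fold (100.9 vs 11.83 CPM, SE 0.153), the helicase subunits Mcm7 and Mcm5 7.18-fold and 7.14-fold, DNApol-epsilon58 6.78-fold, WRNexo 6.73-fold, dpa 6.44-fold and the licensing factor gene dup 6.01-fold (n = 3 each). The receptor gene mthl8 rose at least 957-fold, from 0 reads to 17.45 CPM, where a strain variant between the crosses cannot be told apart from an effect of Spitz. CG11893 fell 40.7-fold, CG6912 23-fold, CR45600 22.1-fold, the antibacterial peptide gene AttD 16.5-fold, mspo 14.5-fold, the peptidoglycan receptor gene PGRP-SD 13.2-fold, Mec2 12.2-fold and the cytokine gene upd2 9.45-fold. Of 10382 genes 3406 changed (32.8%), 1842 higher and 1564 lower, and 968 by at least 2-fold.

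Within the lists, 38 of 49 cell cycle genes rose with Spitz at 8 h and 0 fell (39 and 1 adjusted over the list alone; median 1.27, adjusted p = 8.6e-19; adjusted p = 0.74 with an estimated correlation), as did 28 of 29 respiration genes (median 0.63, adjusted p = 4.53e-15; adjusted p = 0.74 with an estimated correlation). Immune genes fell in 8 of 18 (adjusted p = 0.00429; adjusted p = 0.768 with an estimated correlation), including Rel, the NF-kappaB factor of the IMD pathway, by 2.87-fold (2034 to 709.4 CPM). JAK-STAT genes fell in 5 of 13 with 1 higher (adjusted p = 0.0347; adjusted p = 0.693 with an estimated correlation), upd3 by 3.13-fold. Stem cell markers fell in 7 of 14 (adjusted p = 0.00601; adjusted p = 0.792 with an estimated correlation), mira by 3.66-fold and Kr-h1 by 2.28-fold. Enteroendocrine markers fell in 3 of 26 (2 adjusted over the list alone; adjusted p = 0.00566; adjusted p = 0.838 with an estimated correlation), CCHa1 by 2.31-fold. Spitz replicate 1 stood apart, with 13150 CPM of digestive enzymes against 1797 and 2256 CPM and 548.4 CPM of enteroendocrine markers against 1364 and 1946 CPM in the other replicates. Without it and control replicate 3 of the 24 h group, 8 digestive enzymes were lower in place of 1, and 6 enterocyte identity genes in place of 3. Lists that did not pass included EGFR-Ras-MAPK genes, with 5 of 30 higher and 8 lower: Ets21C fell 4.73-fold (646.7 to 136.6 CPM), the neuregulin-like ligand gene vn 5.32-fold and rho 3.22-fold. Higher and lower counts were 10 and 5 of 28 for ribosome biogenesis, 6 and 5 of 31 for detoxification, 2 and 5 of 20 for JNK genes (Mmp1 down 3.6-fold), 7 and 3 of 22 for integrin and adhesion genes and 1 and 1 of 13 for Notch targets.

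By 24 h Spitz had changed 5774 genes (55.6%), 2796 higher and 2978 lower, and beyond 2-fold there were 848 rises and 1657 falls. The follistatin gene Fs rose 21.6-fold (11.95 vs 0.5548 CPM, SE 0.36), the glutathione transferase gene GstD10 12.1-fold, CG44098 54.6-fold and CG9029 15.8-fold, and mthl8 at least 1690-fold (25.94 CPM against 0 reads; n = 3 each). At mthl8 a strain variant between the crosses again cannot be told apart from an effect of Spitz. CG11893 fell 91-fold, CG6912 82.9-fold, Eaat2 82.9-fold, CR45600 117-fold and CG3819 35.6-fold, while lcs, whe and CG16826 fell 664-fold, 550-fold and 475-fold with SEs of 2.65 and 2.68 for the first pair. Stem cell markers fell in 9 of 14 with 0 higher (median dropped by 0.86, adjusted p = 0.00525; adjusted p = 0.792 with an estimated correlation), mira by 11.8-fold (583.9 to 49.6 CPM, SE 0.227), jumu 6.08-fold, Sox21a 2.34-fold and esg 1.93-fold. Notch targets fell in 11 of 13 (adjusted p = 0.000408; adjusted p = 0.74 with an estimated correlation), E(spl)mgamma-HLH by 9.94-fold and klu by 4.04-fold.

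Lists of genes of differentiated gut cells passed downward with Spitz at 24 h. Digestive enzymes fell in 42 of 49 with 1 higher (43 and 1 adjusted over the list alone; median dropped by 2.64, adjusted p = 1.29e-05; adjusted p = 0.911 with an estimated correlation), deltaTry by 20.4-fold and LManIII by 32.9-fold, LysS being the 1 that rose (26.7-fold). Enteroendocrine markers fell in 19 of 26 with 1 higher (adjusted p = 1.29e-05; adjusted p = 0.792 with an estimated correlation), the peptide hormone genes Dh31 and AstC by 19.9-fold and 6.63-fold. Enterocyte identity genes fell in 8 of 18 with 1 higher (6 and 1 adjusted over the list alone; adjusted p = 0.0399; adjusted p = 0.838 with an estimated correlation), Myo61F by 2.91-fold. Visceral muscle genes, markers of a cell type outside the sort, fell in 13 of 18 (14 adjusted over the list alone; adjusted p = 0.00535; adjusted p = 0.838 with an estimated correlation), Act57B by 7.02-fold. Digestive enzymes summed to 8374, 7967 and 2288 CPM in controls and 463.6, 1471 and 588.5 CPM with Spitz. Enteroendocrine markers summed to 2328, 2310 and 3552 CPM in controls and to 539.6, 744.6 and 679.1 CPM with Spitz. The sums of muscle genes overlapped, with 2981, 2407 and 2472 CPM in controls and 2359, 2565 and 2012 CPM with Spitz. Those of enterocyte identity genes also did (2821, 2746 and 2411 CPM in controls, 1590, 2609 and 2154 CPM with Spitz). With control replicate 3 and the 8 h Spitz library left out, 43 digestive enzymes and 9 stem cell markers were lower, and 1 of each list was higher. Blood, fat body and ovary markers split 2 up (Ilp6, 3.96-fold, and NimC1, 9.21-fold) and 5 down of 13. Their sum was 196.6, 197.9 and 197.8 CPM in controls and 276.4, 259.7 and 269 CPM with Spitz.

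Respiration genes rose in 29 of 29 with Spitz at 24 h (median 0.81, adjusted p = 2.22e-14; adjusted p = 0.74 with an estimated correlation), ATPsynO by 2.19-fold. Detoxification genes rose in 19 of 31 and fell in 4 (20 and 4 adjusted over the list alone; median 0.87, adjusted p = 0.000244; adjusted p = 0.838 with an estimated correlation), GstD1 by 3.84-fold (4423 vs 1151 CPM) and the peroxiredoxin gene Jafrac1 by 2.3-fold. Integrin, basement membrane and adhesion genes rose in 13 of 22 and fell in 4 (adjusted p = 0.0399; adjusted p = 0.838 with an estimated correlation), the collagen IV genes Col4a1 and vkg by 17.5-fold and 12-fold from under 1 CPM. Metabolic genes rose in 13 of 24 and fell in 4 (adjusted p = 0.0178; adjusted p = 0.74 with an estimated correlation), mdy, a triglyceride synthesis gene, by 3-fold. Immune genes fell in 11 of 18 (adjusted p = 0.0111; adjusted p = 0.792 with an estimated correlation), PGRP-SC1b by 10.2-fold, and JAK-STAT genes in 7 of 13 with 1 higher (8 and 1 adjusted over the list alone; adjusted p = 0.0236; adjusted p = 0.693 with an estimated correlation), et by 12.1-fold and Socs36E by 2.19-fold. Cell cycle genes did not pass as a list, with 17 of 49 higher and 9 lower, though PCNA rose 3.07-fold and Mcm7 3.84-fold. Nor did heat shock genes, 6 up and 2 down of 18, although the endoplasmic reticulum chaperone gene Hsc70-3 rose 3.34-fold to 18070 CPM. EGFR-Ras-MAPK genes split 6 up and 10 down of 30, ribosome biogenesis 7 and 10 of 28 and JNK genes 8 and 3 of 20.

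**Figure D2:**
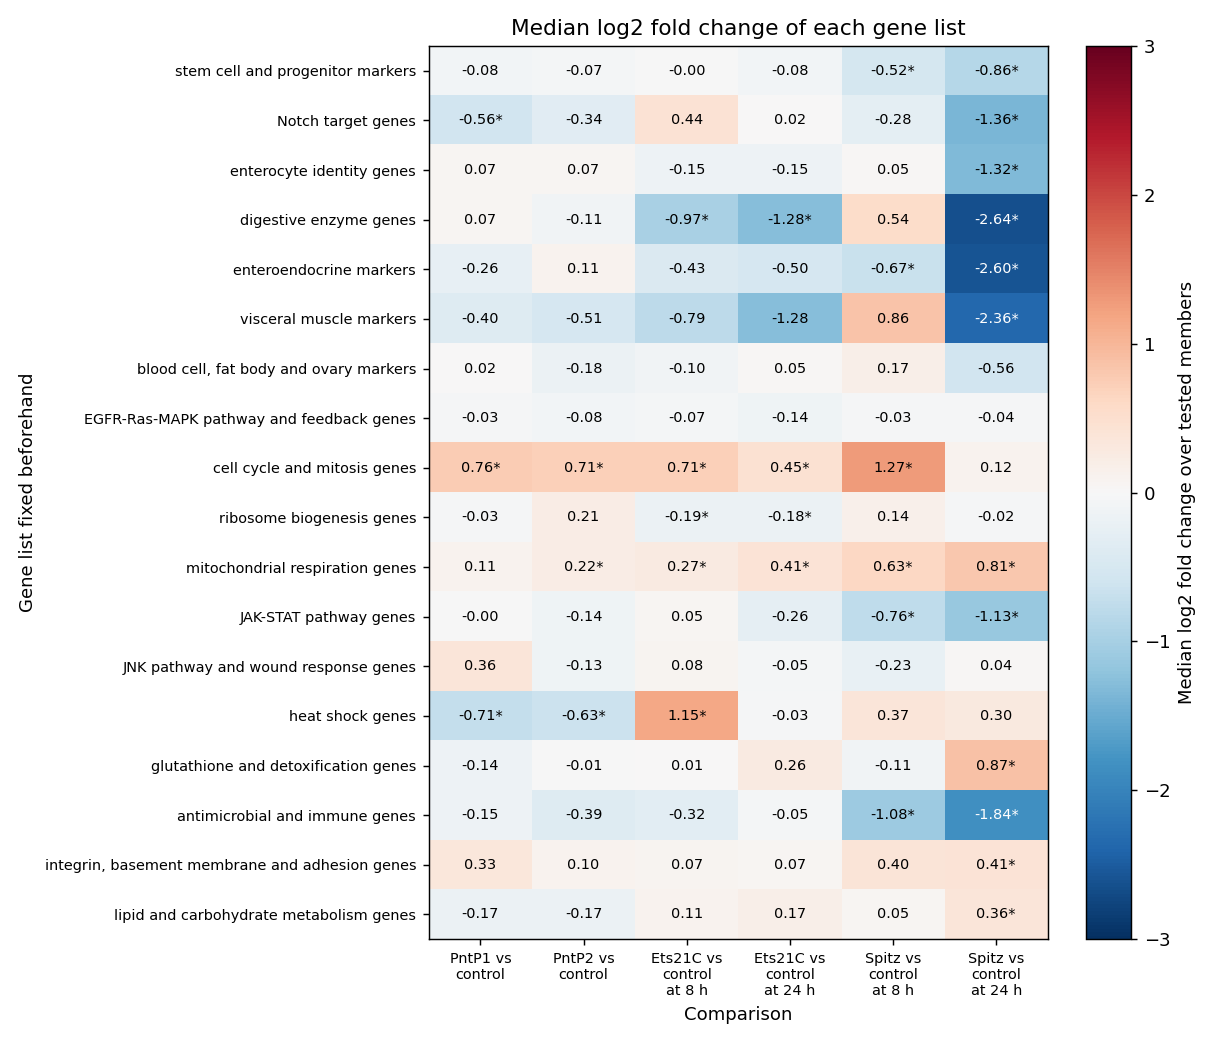
Median log2 fold change of the tested members of each of the 18 gene lists (vertical axis) in the 6 comparisons with control (horizontal axis); colour and number give the median and a star marks a camera adjusted p under 0.05 at the preset correlation. Cell cycle medians are 0.76 with PntP1 and 1.27 with Spitz at 8 h.

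The Spitz effect differed between 24 h and 8 h at 1630 genes, with 794 more positive and 836 more negative at 24 h, and at 817 of them by at least 2-fold. The glutathione transferase genes GstD2 and GstD5 gained 8.12-fold (3233 CPM at 24 h against 394 CPM in its controls for GstD2; SE 0.591) and 6.61-fold, and the noncoding genes CR45973, CR44522 and CR46089 9.58-fold, 9.4-fold and 7.87-fold. The glutamate transporter gene dmGlut and LManV lost 52.3-fold and 45.9-fold, and lcs, whe and CG16826 also lost at 24 h, the calls of whe and CG16826 each ending when single libraries were left out (whe without control replicate 1 or Spitz replicate 2 at 8 h or any Spitz library at 24 h, CG16826 without Spitz replicate 2 at 8 h or replicate 1 or 3 at 24 h). Without control replicate 2 at 24 h the count was 805, without Spitz replicate 3 at 24 h 878 and without control replicate 2 at 8 h 1068. Spitz raised 1406 genes and lowered 1051 at both times, against 496 and 449 by independent lists, with 79 in opposite directions. The spi transcript itself differed by 1.26-fold, which did not pass (adjusted p = 0.164).

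Ets21C and Spitz libraries at 24 h differed directly at 4712 genes (45.4%), 2282 higher and 2430 lower with Ets21C, and at 1778 by at least 2-fold. Gr59e was 338-fold higher with Ets21C (SE 0.547), CG11893 176-fold, CG32305 at least 1550-fold, CG32301 at least 839-fold and CG34113 at least 543-fold, while mthl8 was at least 1420-fold lower, Tektin-C 129-fold, CG9029 35.3-fold, Drat 22.1-fold and hbs 15.2-fold lower (n = 3 each). At the near-silent genes among these a strain variant between the crosses cannot be told apart. Ets21C itself was 6.12-fold higher (SE 0.245). Against their shared controls both proteins raised 737 genes and lowered 620, with 211 opposite. Independent lists would share 321 and 313. Simulated unchanged groups shared 0, which here and at 8 h sets no bound on the part due to the controls, as no simulated gene changed. The correlation of fold changes was 0.492 (simulated 0.47) and the covariance 0.755 (simulated 0.118). At 8 h the overlaps were 387 and 329, with 157 opposite (150 and 117 by independent lists, 0 simulated), the correlation 0.287 (simulated 0.439) and the covariance 0.313 (simulated 0.127). Part of these excesses may come from the shared controls.

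Between sets, whose controls were separate, PntP1 and Ets21C at 24 h both raised 357 genes and both lowered 401, with 162 opposite (189 and 157 by independent lists; correlation 0.166). PntP2 and Ets21C shared 232 and 244, with 61 opposite (94.6 and 67.8; correlation 0.27). For PntP1 and Spitz at 24 h the overlaps were 563 and 493 with 691 opposite (447 and 406; correlation 0.0414), and at 8 h 458 and 380 with 390 opposite (303 and 222). PntP2 and Spitz at 24 h shared 316 and 251 with 262 opposite (224 and 176).

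DamID asked where each factor was found in stem cells. The same window of 75 bp on chromosome 3L, 20242876 to 20242951, assigned to Clc (clathrin light chain) and CG6951, led all 3 fusions, at least 168-fold above Dam with Ets21C-Dam (n = 4 each), 75.4-fold with PntP1-Dam (SE 0.557) and 131-fold with PntP2-Dam (SE 0.565; n = 5 each). Ets21C-Dam also gave windows at mthl8 (3L, 25126 to 25201, at least 94.3-fold) and CG31886 (2L, 8955226 to 8955301, at least 95.6-fold). Dam alone gave 0 reads in both windows and, in the Ets21C set, also in the Clc window. At these windows a strain variant between the crosses cannot be told apart from a site of Ets21C-Dam. In the Pnt set Dam alone gave 17 reads in the Clc window, against 966 with PntP1-Dam and 1227 with PntP2-Dam, which leaves a strain variant open there too. PntP1-Dam stood 52.4-fold above Dam at 3R, 30488251 to 30488326, where no gene was assigned, and 40.9-fold at CG33144 (2R, 10772626 to 10772701). PntP2-Dam stood 75.1-fold above Dam at the same 3R window and 77-fold at 4, 1288651 to 1288726, with ratios of 106 (28.8 to 886) at tou and 115 (31.1 to 957) at vn.

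The 5 EGFR pathway genes of the naming rule each held windows above Dam in each map, although over strata of gene length the pathway's list did not pass for peaks of PntP1, PntP2 or Ets21C (adjusted p = 0.127, 0.683 and 0.22, a test chosen after the data were seen). In pnt itself, PntP1-Dam rose 30-fold over Dam (3R, from 23292001; 158 of 547 windows higher), PntP2-Dam 11.1-fold (from 23291926; 357 of 547) and Ets21C-Dam 8.84-fold (from 23298001; 303 of 512). At a fusion's own gene (pnt for the Pnt fusions, Ets21C for Ets21C-Dam) reads of the transgene were not separated, so binding there cannot be told apart from them. In Ets21C the highest windows were 14.7-fold with Ets21C-Dam, 8.76-fold with PntP1-Dam and 8.89-fold with PntP2-Dam, and in spi 13.8-fold, 8.19-fold and 12.3-fold. In sty, a feedback inhibitor, they were 6.29-fold, 4.97-fold and 9.54-fold, and in aos, a secreted inhibitor, 8.18-fold, 3.65-fold and 6.47-fold. The stem cell gene esg had its highest window 3.74-fold above Dam with PntP1-Dam (10 of 31 windows higher) and 5.88-fold with PntP2-Dam (31 of 31). With Ets21C-Dam the highest esg window was 2.75-fold above Dam (25 of 26 windows higher). The call of that highest window was lost under total-count scaling (log2 1.024) and without control replicate 1 (1.405) or 2 (1.295). Dl, the Notch ligand gene, reached 4.03-fold, 2.63-fold and 4.74-fold with Ets21C-Dam, PntP1-Dam and PntP2-Dam, the PntP1-Dam call being lost under total-count scaling (log2 0.995). Of its windows 33 of 285, 11 of 290 and 94 of 290 were higher, and 14, 1 and 11 were lower. The mitotic phosphatase gene stg reached 3.96-fold with PntP1-Dam and 4-fold with PntP2-Dam. With Ets21C-Dam it reached 2.12-fold, and the call was lost under total-count scaling (log2 0.655), without Dam replicate 1, 2 or 4 (1.129, 0.949 and 0.907) and without Ets21C-Dam replicate 2 or 3 (1.013 and 1.128). E(spl)mbeta-HLH reached 6.42-fold, 7.44-fold and 11.6-fold in the order of Ets21C-Dam, PntP1-Dam and PntP2-Dam. In the same order E(spl)malpha-BFM had 8 of 8, 3 of 10 and 10 of 10 windows higher. E(spl)mgamma-HLH had 7 of 7 with Ets21C-Dam and 11 of 12 with PntP2-Dam, E(spl)m3-HLH 2 of 6 and 6 of 12, and E(spl)m2-BFM 10 of 14 with PntP2-Dam. For PntP2-Dam the named windows of E(spl)mgamma-HLH, E(spl)m3-HLH and E(spl)m2-BFM lost their calls under total-count scaling (log2 1.012, 0.797 and 0.798), and for Ets21C-Dam that of E(spl)m3-HLH without Dam replicate 2 (1.572). E(spl)m4-BFM, E(spl)m5-HLH, E(spl)m8-HLH and E(spl)mdelta-HLH had no higher window in any map, the last with 2 windows lower with PntP2-Dam. With the replicate number as a block, PntP1-Dam also passed upward at the named windows of E(spl)m2-BFM, E(spl)m3-HLH and E(spl)m8-HLH (log2 0.707, 1.028 and 0.985), and that of E(spl)mdelta-HLH fell by 0.871 on the log2 scale. PntP2-Dam with this block also passed upward at the named window of E(spl)m8-HLH (log2 0.65) and downward at that of E(spl)mdelta-HLH (log2 -0.578).

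Of 723908 windows tested, 223539 differed with Ets21C-Dam (30.9%), 117993 higher and 105546 lower. Of 834870 in the Pnt set, 124162 differed with PntP1-Dam (14.9%; 82511 and 41651), 458697 with PntP2-Dam (54.9%; 209484 and 249213) and 219381 between the fusions (26.3%; 133066 higher with PntP1-Dam and 86315 lower). Scaling by total counts moved the median log2 change from 0.02 to -0.41 for Ets21C-Dam, from -0.05 to -0.42 for PntP1-Dam, from -0.17 to -0.93 for PntP2-Dam and from 0.10 to 0.48 between the fusions. The splits of higher and lower windows then became 62980 and 178411, 41719 and 120540, 95394 and 423356, and 229038 and 31273, so that more windows were higher than lower for Ets21C-Dam and PntP1-Dam with TMM and not with this scaling. With the replicate number as a block PntP1-Dam differed at 270520 windows (154566 higher, 115954 lower) and the fusions at 362079 (190753 and 171326). Without Dam replicate 1, 2 or 4 the PntP1-Dam count was 74564, 75830 or 82559. On every 20th window both Pnt fusions were higher at 3792 and lower at 1868, with 6 opposite (1030 and 619 by independent lists), with a correlation of 0.751 (simulated 0.473), a covariance of 0.79 (simulated 0.0793) and a median correlation of 0.6455 over splits of the controls (0.536 to 0.741). Over those splits, with fewer control libraries per comparison, the median overlaps were 272.5 higher and 138.5 lower. Same-numbered PntP1-Dam and PntP2-Dam libraries also deviated together (0.229 to 0.553), which the simulated values leave out, so part of the excess may come from that and from the shared controls.

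The authors' deposited lists held 6075 PntP1, 6292 PntP2 and 6040 Ets21C peaks, each with a median width of 450 bp, assigned to 3689, 3615 and 3272 genes. By the authors' log2 ratios, the highest PntP1 peaks lay at Nckx30C (2L, 9744976 to 9745051, 5.64), RhoGEF64C (4.71), CG14717 (4.68), Clc and CG6951 (4.63) and pnt (3R, 23291926 to 23292151, 4.54). For PntP2 they lay at Clc and CG6951 (4.85), CG14717 (4.55), chromosome 4 from 1288501 (4.41) and Dscam1 (4.12 and 4.04), and for Ets21C at mthl8 (3L, 24526 to 25576, 7.17, and another at 7.15), Clc and CG6951 (5.88), Zasp52 (5.85) and CG31886 (5.79). At pnt transgene reads were not separated, and at mthl8, at CG31886 and at Clc and CG6951 a strain variant cannot be told apart. Of the PntP1 peaks 4052 overlapped a PntP2 peak, 66.7% (95% exact interval 65.5 to 67.9%), against 11.5% for shuffled positions, which leave out that both fusions share their Dam controls. PntP2 peaks overlapped Ets21C peaks in 2030 cases (32.3%; 31.1 to 33.4%; shuffled 9.76%), and PntP1 peaks overlapped Ets21C peaks in 964 (15.9%; 15 to 16.8%; shuffled 9.09%). Among the stronger part of each list PntP1 and Ets21C shared 6.71%, equal to the highest of the shuffles. Overlaps of both other lists were found for 916 PntP1 peaks (15.1%).

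Peaks were commoner at genes that changed expression. Genes are not independent replicates, so the odds ratios, intervals and p-values below describe these lists. A PntP1 peak was assigned to 1241 of 3059 genes changed by PntP1, 40.6% against 29.3% of the others (odds ratio 1.65, 95% interval 1.51 to 1.8, Fisher's exact p = 1.47e-27), a PntP2 peak to 44.7% against 30.3% (1.86, 1.65 to 2.09) and an Ets21C peak to 35.5% against 23.2% of genes at 24 h (1.82, 1.64 to 2.01). With PntP1 and PntP2, genes that fell carried peaks more often than genes that rose. The odds ratio was 2.58 (2.29 to 2.9) for genes lowered by PntP1 and 1.08 (0.957 to 1.22) for genes raised, a ratio of raised to lowered of 0.418 (0.36 to 0.486), and for raised genes it was 1.28 (1.12 to 1.46) over strata of gene length and 0.913 (0.809 to 1.03) over strata of control expression. For PntP2 the values were 3.37 (2.84 to 4.01) and 1.16 (0.993 to 1.36), with 1.55 (1.3 to 1.85) over strata of length and a ratio of 0.345 (0.275 to 0.431). For Ets21C they were 1.98 (1.73 to 2.26) and 1.68 (1.47 to 1.92), and the difference did not pass (0.852, 0.715 to 1.02, Fisher's exact p = 0.0726); over strata of length the order turned, with 1.55 (1.32 to 1.82) for lowered and 1.76 (1.51 to 2.05) for raised genes. Over strata of mean expression the odds ratios for all changed genes were 1.26, 1.41 and 1.57. Genes changed by at least 2-fold were also set against all other genes, smaller changes included, and the odds ratios were then smaller. With PntP1 36.2% of them carried its peak against 32.5% of the others (Fisher's exact p = 0.024). For PntP2 the shares were 39.2% and 32.1%, and for Ets21C at 24 h 35.5% and 25.2%.

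**Figure D3:**
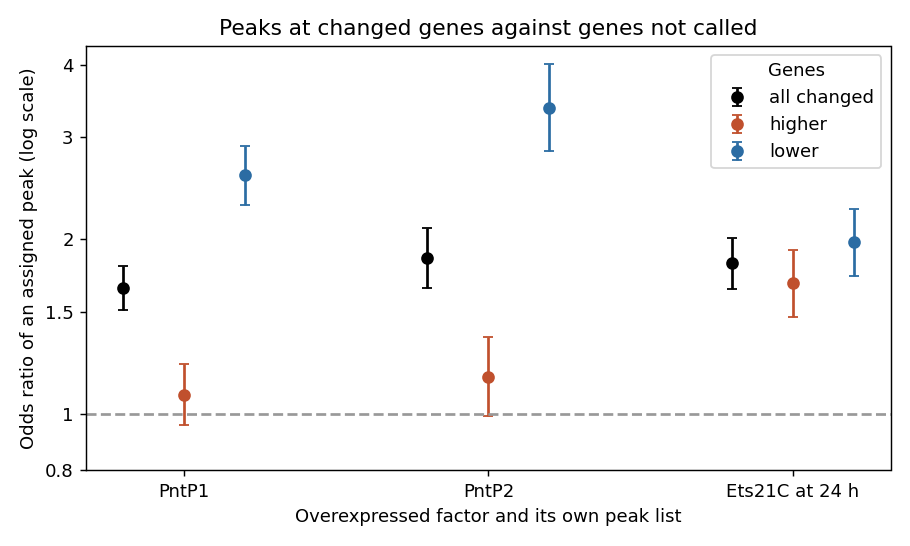
Odds ratio (vertical axis, log scale) of a peak of the factor's own list at genes changed by that factor against genes not called, for PntP1, PntP2 and Ets21C at 24 h (horizontal axis); points are odds ratios for all changed, higher and lower genes and bars are 95% intervals. Lowered genes reach 2.58 with PntP1 and 3.37 with PntP2. The intervals take genes as independent, which they are not.

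The authors' deposited tables called 3097 genes for PntP1, 2244 for PntP2, 2525 and 2358 for Ets21C at 8 h and 24 h, and 3089 and 5494 for Spitz. Their log2 fold changes correlated with those given here at 0.969, 0.858, 0.992, 0.993, 0.989 and 0.991 across genes, in the same order. Genes called in both numbered 2742, 1284, 1486, 1902, 2851 and 5092, all but 3 in the same direction. The authors' deposited lists of direct targets held 388 raised and 597 lowered genes for PntP1 and 298 and 401 for PntP2, each list matching a rule of their own adjusted p, an absolute log2 change of at least 0.5 and a peak.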

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

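Chosen after the results were seen were the tests on genes far from control, on gene length, on blood, fat body and ovary markers and on stem cell markers, on the left-out control library, the logistic model without the Ets21C peak, and the counts over other splits of the Spitz libraries; the tests on expression level and on shared open sites were set beforehand.

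The Spitz effect at 24 h differed from that at 8 h at 1630 genes, which was picked out because the same contrast was tested at both times. Of 100 splits that exchanged Spitz and control libraries within each time 2 called as many, the real one included. The highest other, which put control replicate 3 among the Spitz libraries at 8 h and kept the 24 h groups, called 1949. Such splits mix the effect of Spitz itself into the spread, so whether chance can be excluded is left open. The Ets21C effect differed between the times at 1 gene, CG9338, by edgeR, with 551 at an unadjusted p under 0.05 and 17 by DESeq2. The third value picked out was 1670369 windows with reads in Dam replicate 4 of the Pnt set, a library of 132.9 M counts, against 1583856 to 1607868 in the other 4. It was the 1 sample far from its group in 20 tests, and chance gives about 1 in 20.

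Genes at least 8-fold from control in 1 direction at both 8 h and 24 h numbered 72 for Ets21C (39 higher, 33 lower) and 93 for Spitz (43 and 50). Of these 20 were in both lists, each in the same direction, to which the shared controls may have added, though this was not tested. At least 100 reads were held by 76.4% of the Ets21C genes and 53.8% of the Spitz genes, which leaves low counts open for the rest. Binding by Ets21C stays open: an Ets21C peak lay at 25% of its 72 genes and 40.6% of the other genes called at both times (odds ratio 0.488, 0.266 to 0.859, Fisher's exact p = 0.00886), but the Spitz genes, where Ets21C was not overexpressed, had as low a value (0.505, 0.273 to 0.881). Within 10 kb of another of the set lay 9 Ets21C genes, such as CG32301 with CG32305, against a mean of 1.22 in 10000 random draws (permutation p = 0.0007), and 13 Spitz genes against 1.74 (p = 0.0001, the smallest they can give). A strain variant between the crosses may explain this, but neighbours regulated together would give the same values, and genotype goes with the group. At mthl8, which Spitz raised from 0 reads, DNA of the Dam controls also gave 0 reads in windows where Ets21C-Dam gave 198 to 221.

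Genes lowered by PntP1 carried PntP1 peaks more often than other genes. Expression level as the whole cause is argued against by an odds ratio of 1.84 (1.62 to 2.08) over strata of control CPM, and gene length by 2.26 (1.98 to 2.59) over strata of length. With the Ets21C peak, length and expression in 1 logistic model the odds ratio was 1.45 (1.26 to 1.68), against 1.53 (1.33 to 1.77) on the same genes without the Ets21C peak. This argues against genes shared with the Ets21C list as the whole cause. Sites open to any fusion protein stay open as a cause, since openness was not measured and only 15.9% of PntP1 peaks overlapped an Ets21C peak. Expression and length may each account for part of the unadjusted 2.58. Repression by PntP1 at the genes it binds is a hypothesis that stays open and was not tested apart from these.

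With Spitz at 24 h digestive enzyme, enteroendocrine and muscle genes fell together, the medians by 2.64, 2.6 and 2.36 on the log2 scale. The summed CPM of muscle genes, unlike those of enzymes and enteroendocrine markers, overlapped between the groups (2407 to 2981 in controls, 2012 to 2565 with Spitz). The control library that stood apart was the highest control for enteroendocrine markers and is argued against as the cause of their fall, since 19 of 26 stayed lower without it and the 8 h Spitz library that stood apart; for enzymes it was the lowest control, so the 43 of 49 lower without it decide nothing. A lower share of other cells among the sorted cells could lower all 3 lists alike. Blood, fat body and ovary markers fell less, by a difference of 2.08 (13 against 93 genes, permutation p = 0.00035), but only 2 of them reached 10 CPM in controls, so this cannot be told apart. For the stem cell markers such a change alone would give a rise only if they marked stem cells alone. Their median was -0.858, with 9 of 14 lower and none higher. Without the 2 libraries that stood apart 9 were lower and 1 was higher, with a median of -0.748, so the prediction that none rises was not met there. The list also holds progenitor markers, which other sorted cells may carry, so a lower share of other cells stays open for it. A change of state of the stem cells under Spitz stays open as untested.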

How the results depend on the processing

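The fit without 2 libraries that stood apart and the older DamID dispersion route were chosen after seeing the data. No named gene or window that passed in the main fit or an alternative reversed between them. Over all alternatives 398 values no longer passed, 87 newly passed and 7258 did neither. Among the 7258, direction was not compared for values that passed in neither fit, and values without an adjusted p were counted as the same. All named calls were kept for Spitz at 24 h (88) and Ets21C against Spitz (11), while 46 of 69 were lost somewhere for PntP2, 27 of 74 for Ets21C at 8 h, 13 of 76 at 24 h, 11 of 85 for PntP1 and 9 of 75 for Spitz at 8 h. For PntP1 against PntP2 10 of 10 were lost somewhere, for the Ets21C time effect 1 of 1 and for the Spitz time effect 2 of 10. Of the summary values 180 stayed the same and 50 moved, a count being taken as moved when it changed by over 1.5 times. The cause was not tested except where fewer libraries or a stricter limit shows it. A log2 change of at least 1 left 914, 408, 542, 710, 968, 2505, 1778 and 817 genes for PntP1, PntP2, Ets21C at 8 h and 24 h, Spitz at 8 h and 24 h, Ets21C against Spitz and the Spitz time effect, which that stricter limit explains. With the replicate block Ets21C at 8 h gave 951, PntP1 against PntP2 151, the Ets21C time effect 0, PntP1-Dam 270520 windows and the Pnt fusions 362079; the block moved no other count by over 1.5 times, and 32 of the 33 list calls passed with it, all but digestive enzymes with Ets21C at 8 h (adjusted p = 0.0619). PntP1 against PntP2 gave 146 with no filter, 239 with only the compared groups and 266 by DESeq2. The Ets21C time effect gave 0 at 10 CPM, 3 without the libraries that stood apart and 17 by DESeq2. Peak overlaps moved to 58.2% for the stronger part of the PntP1 and PntP2 lists, to 14.4% and 6.71% for PntP1 and Ets21C with a larger overlap asked for and in the stronger part, and to 30.9% and 24.9% for PntP2 and Ets21C. Odds ratios of peaks over all changed genes of a factor kept their side of the threshold. For genes changed by at least 2-fold they were smaller for each factor. By direction, odds ratios of raised genes newly passed over strata of gene length for PntP1 (1.28) and PntP2 (1.55). With an estimated correlation 0 lists passed. Leaving out 1 library gave ranges of 1852 to 3880 for PntP1, 127 to 2323 for PntP2, 585 to 1338 for Ets21C at 8 h, 1533 to 2160 at 24 h, 2798 to 3258 for Spitz at 8 h, 4718 to 5547 at 24 h, 0 to 53 for PntP1 against PntP2, 3722 to 4572 for Ets21C against Spitz, 0 to 1 for the Ets21C and 805 to 1687 for the Spitz time effect, and, in windows, 153448 to 309240 for Ets21C-Dam, 74564 to 151084 for PntP1-Dam, 426578 to 469769 for PntP2-Dam and 177228 to 215987 between the fusions. Where 1 PntP2 or 8 h Ets21C library was left, it was assumed to vary like the other groups.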

Other observations

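The counts of peaks over the gene lists and over other splits of the libraries were chosen after the results were seen.

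By the authors' assignment, peaks were commoner at stem cell markers for PntP2 and Ets21C, and at Notch targets for PntP1 and Ets21C. Of 14 stem cell markers 12 had a PntP1 peak, 13 a PntP2 peak and 13 an Ets21C peak, among them esg, Dl, N, mira, Sox21a and ttk in all 3 lists (adjusted p = 0.0763, 0.0262 and 0.0253 over strata of gene length, 54 tests, the first not passing). Notch targets had a PntP1 peak in 9 of 13 and an Ets21C peak in 9 of 13, including klu, E(spl)mbeta-HLH and E(spl)malpha-BFM (0.00167 and 0.000109), and a PntP2 peak in 4 (0.846). The E(spl) genes lie together on 3R (25997621 to 26041008), so a peak may count for several of them, while the test takes genes as independent. Of those counted for PntP1, E(spl)m2-BFM, E(spl)m5-HLH, E(spl)m7-HLH, E(spl)m8-HLH and E(spl)mdelta-HLH held no PntP1-Dam window above Dam in the fit without a replicate block. By windows, PntP2-Dam was above Dam in E(spl)m2-BFM, E(spl)m3-HLH and E(spl)mgamma-HLH, calls that were lost under total-count scaling (log2 0.798, 0.797 and 1.012), and PntP1-Dam in the first 2 of these with the replicate number as a block (0.707 and 1.028); the fusions were not compared at these windows. EGFR-Ras-MAPK genes had peaks in 21, 18 and 20 of 30, among them aos, Cbl, edl, Mkp3 and sty in all 3, which over strata of length did not pass (0.127, 0.683 and 0.22). Metabolic genes had a PntP1 peak in 16 of 24 (0.0262), bmm and mdy among them, while cell cycle genes had peaks in 17, 11 and 9 of 49 and digestive enzymes in 6 of 49 for each factor.

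Other splits of the libraries into groups of the same sizes were fitted in the same way. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and the real split was the 1 with the highest count in each case: 3059 for PntP1, 2283 for Ets21C at 24 h, 3406 and 5774 for Spitz at 8 h and 24 h and 4712 for Ets21C against Spitz, with 0 as the highest other. For DamID, on every 20th window, the real split of Ets21C-Dam was the only 1 of 35 as high (11098, highest other 0). That excludes chance at 0.05 only if its libraries are not paired. Of the same-numbered pairs 2 deviated together (0.565 and 0.726) and the others did not (-0.227 and 0.0603), so whether chance can be excluded is left open. The real split was also the only 1 of 100 as high for PntP1-Dam (6163, highest other 3881), PntP2-Dam (23084, 7333) and between the Pnt fusions (10927, 1061). Only 16 splits part every pair of same-numbered libraries as the real one does, too few for a share under 0.05 in these 3 comparisons. Among them the highest others were 82, 2 and 0, so the higher counts came from splits that kept some of these pairs together.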
